A study of Mus musculus with 34 samples.

How the data were processed

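Mouse liver samples were profiled by RNA sequencing. Per the labels' protocols, tumours were modelled by hydrodynamic injection, a rapid large-volume injection that delivers plasmids to hepatocytes, and total RNA from frozen liver tumours was made into strand-specific libraries. The 34 libraries fall into 9 groups by their source label: 2 wild type livers, 3 livers with the beta-catenin skip1 isoform alone, 2 with the skip2 isoform alone, 5 skip1 induced, 2 skip2 induced and 4 dN90 induced samples (beta-catenin lacking its N terminus), 4 subtype A and 9 subtype B tumours, and 3 samples with a guide against actin and YAPS127A, an activated form of YAP. For the 4 skip2 samples the source label says skip2 while another label field repeats skip1. The source label was used. Replicate numbers were given in accession order and pair no samples. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure the spread between these samples only.

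The first deposited table held normalized counts, a non-negative signal per gene, for 14086 genes in 18 libraries. Per the submitters' processing notes, the build was mm10 and FastQC, STAR, RSEM and DESeq2 were used, with no versions or settings given in the sources used here. About 60% of the values above 0 were whole multiples, within 0.001, of 1 step per library, so estimated reads were taken as the column sum divided by that step. They ranged from 361772 to 933147 per library, which limits the precision of low genes. The depth of the z-scored libraries is not known. The second deposited table held a score: from the deposited values, the authors centred and scaled each of 1659 genes to a z-score before deposit, on genes that they selected by a rule not given in the sources used here. From the values, 16 libraries (subtype A, subtype B and the actin guide control) were scaled together with 1 further library that is not a column, and the other 18 libraries were scaled apart. A z-score difference is in SDs of a gene over its block and gives no fold. Gene selection means that counts of called genes in the second table cannot be read as a share of the transcriptome. The 2 blocks were never tested against each other. No column of per-sample values was left unused.

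For the normalized counts, genes with a mean of at least 10 over the 18 libraries were kept (6592 genes) and log2(value + 1) was tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per group, a trended prior, two-sided tests and Benjamini-Hochberg adjustment. Genes were called at an adjusted p under 0.05. A difference on the log2(value + 1) scale understates the change of low genes. The design fixed before the data were examined assumed log-scale values for the subtypes too; because that table holds z-scores, limma without a trend was applied to the z-scores of the 16 libraries. The 28 gene lists were fixed beforehand and tested on the normalized counts with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over lists. Lists were only counted for the z-scores, since those genes were selected by the authors. No members of the T and NK cell, B cell, neutrophil or mitochondrial genome lists were among the genes tested.

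Named genes followed a rule fixed beforehand. Per comparison it took up to 8 genes per direction with the largest differences among called, non-overlapping genes with a mean of at least 100 in the higher group, up to 4 called members per list, and 10 genes in every comparison, of which Lgr5, Krt19, Afp and Ccn2 were not among the genes kept in the normalized counts, and Ctnnb1, Glul, Yap1, Lgr5, Krt19 and Ccn2 were not among the z-scored genes. The text names part of what the rule selects. Of the 14086 symbols, 98.3% matched the reference names, and coordinates are from GENCODE on the mm10 build.

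Alternatives fixed beforehand were other pseudocounts (0.5 and 5), no filter and a mean of at least 50, upper-quartile and quantile scaling, a fit on only the compared groups, array weights and leaving out each replicate. Added after the data were seen were voom on estimated reads, log2 depth as a covariate, leaving out skip1 induced replicates 1 and 2 together, rescaled z-scores and an exact permutation test per gene. Voom scaled each library by its total of estimated reads, which replaced the scaling of the deposited values. The test was checked on simulated data with 200 changed genes. A single run drew normal noise independently for each gene and library, with the same spread of a gene in all groups. It held no correlation between genes and no difference in depth, so its shares need not hold for these data. For skip1 against skip2 induced (6592 genes) it called 32% of genes changed by 1 log2 unit and 85% of those changed by 2, and 5.65% of calls were false. For skip1 alone against wild type it called 30% and 90%, and for skip2 alone against wild type 18% and 74%. For subtype A against B (1659 genes) it called 59% of genes shifted by 0.5 SD and 87% of those shifted by 1 SD, with 7.59% false calls. The share of false calls was highest for skip2 induced against skip2 alone, at 9.35%, where 26% of genes changed by 1 log2 unit and 71% of those changed by 2 were called. Pairs of libraries within a group were compared by chi-square on estimated reads. Chi-square per degree of freedom lay between 2.52 and 11.9 over 22 pairs, so no pair agreed within sampling noise.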

Results

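The series asks what sets apart the subtypes of mouse liver tumour that arise with beta-catenin isoforms lacking an exon. Normalized counts were available for wild type liver (2 libraries), skip1 alone (3), skip2 alone (2), skip1 induced (5), skip2 induced (2) and dN90 induced (4) samples. Z-scores of selected genes were available for subtype A (4), subtype B (9) and the control with an actin guide and YAPS127A (3). Estimated reads per library ran from 361772 in dN90 induced replicate 3 to 933147 in skip2 induced replicate 1, and skip2 induced replicate 2 was next at 815420. The depth of the z-scored libraries is unknown.

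Ctnnb1, the gene for beta-catenin (chromosome 9, 120929216 to 120960507, mm10), was measured first. Its normalized count was 804 ± 268 (SD, n = 5) in skip1 induced and 451 ± 9.06 (n = 2) in skip2 induced samples. It was 163 ± 27.8 (n = 4) in dN90 induced samples, 138 ± 14.1 (n = 2) in wild type liver, 141 ± 14.2 (n = 3) with skip1 alone and 160 ± 24.1 (n = 2) with skip2 alone. Gene-level values do not tell isoforms apart, so they do not check which exon was skipped. The level of Ctnnb1 in dN90 induced samples was close to that of wild type liver, a pair that was not tested, so this gene gives no sign of the transgene in those samples. Yap1, the transcriptional coactivator of the Hippo pathway, had means between 33 and 39.8 in the 6 groups and passed no test.

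**Figure D1:**
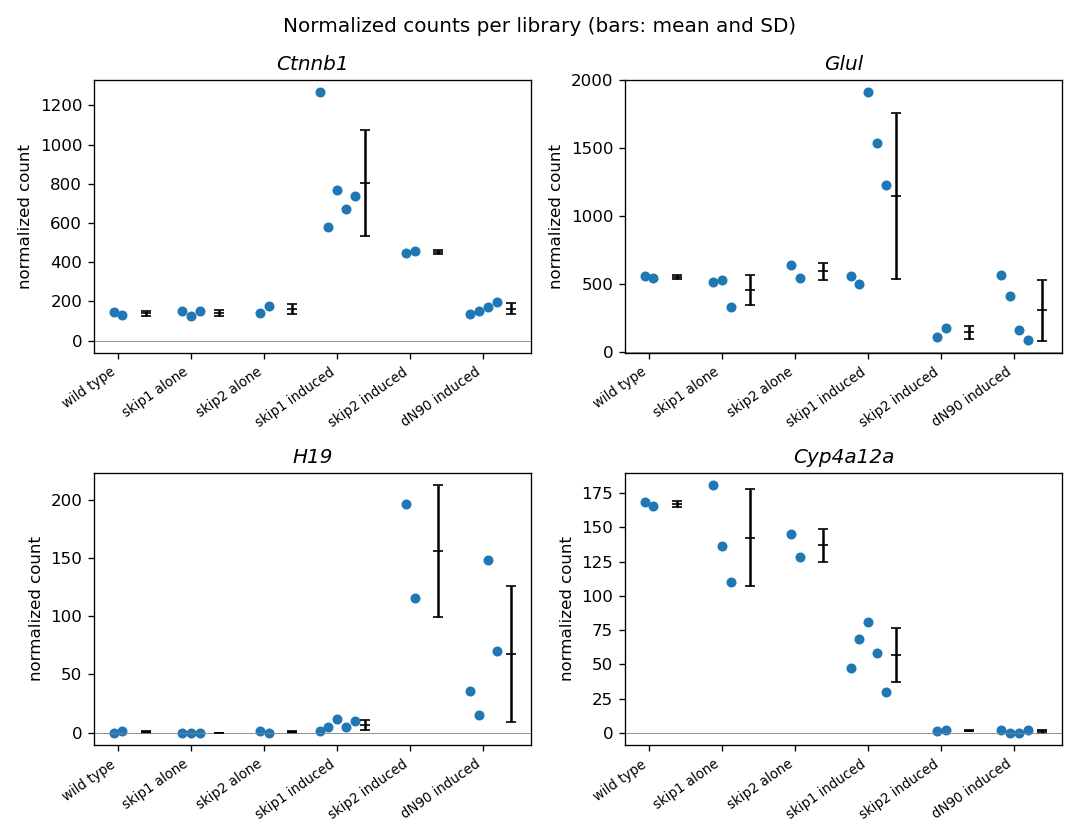
Normalized counts of Ctnnb1, Glul, H19 and Cyp4a12a in each of the 18 libraries by group, with the group mean and SD beside the points. Ctnnb1 lies between 580.2 and 1266 in skip1 induced and between 135 and 199 in dN90 induced samples, and the mean of H19 is highest, at 156, in skip2 induced samples.

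The first comparison asked how skip1 and skip2 induced samples differ. Glul, the glutamine synthetase of pericentral hepatocytes (chromosome 1, 153899944 to 153909723), stood at 1147 ± 614 (n = 5) in skip1 and 142 ± 45.7 (n = 2) in skip2 induced samples, a log2 difference of 2.85 (SE 0.55, limma adjusted p = 0.0073). The glutamate transporter gene Slc1a2 (2.84) was also higher with skip1. Of 18 pericentral genes 3 were higher, or 4 higher and 1 lower when adjusted over the list alone, and that list did not pass camera (adjusted p = 0.0525). H19, an imprinted non-coding RNA of fetal liver (chromosome 7, 142575529 to 142578143), went the other way, at 6.6 ± 4.34 against 156 ± 56.6 (log2 difference -4.57, SE 0.73, limma adjusted p = 0.00182). Igfbp2, which encodes an insulin-like growth factor binding protein, was also lower with skip1 (-2.90, SE 0.38).

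Of 7 measured genes with known male-biased expression in mouse liver, 6 were higher in skip1 than in skip2 induced samples, and 7 when adjusted over the list alone. Cyp4a12a was at 57.1 ± 19.7 against 1.58 ± 0.288 (4.42, SE 0.43), Hsd3b5 differed by 3.76 and Mup21 by 3.34, and Elovl3 was listed at 0 in both skip2 libraries. The list passed camera (adjusted p = 3.42e-12) and held with an estimated correlation (adjusted p = 0.00332). Among 24 hepatocyte function genes, G6pc, the glucose-6-phosphatase of glucose output (1.95), and Fabp1, a fatty acid binding protein gene (1.30), were higher and Ahsg, a plasma protein gene (-1.13), was lower, the same counts when adjusted over the list alone. The carboxylesterase gene Ces3a (2.86), the serpin gene Serpina3k (3.24) and Mup3 (3.03), a major urinary protein gene whose reads may be shared with its paralogs, were higher, as were the bile acid list's Slco1a1 (2.08) and Cyp7b1 (1.65), 2 of 14, or 3 higher and 1 lower when adjusted over the list alone. In the cholesterol synthesis list 2 of 20 members were lower with skip1, among them the synthase gene Hmgcs1 (-1.01), and 8 when adjusted over the list alone. That list passed camera (adjusted p = 1.02e-06), but not with an estimated correlation (adjusted p = 0.374). Acsl4 (-1.38), Cp (-1.15), Eppk1 (-1.26), Nid1 (-1.11) and Notch2 (-0.92) were lower with skip1, and Hectd2 (3.93), Alas2 (1.48), Aurka (1.39) and Bst2 (1.13) higher. Ctnnb1 (0.78, adjusted p = 0.0846 in limma), Axin2 (0.18), Mki67 (-0.12) and Alb (-0.54) did not pass the test.

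In all, limma called 233 of 6592 genes, 204 higher and 29 lower with skip1. With quantile normalization the split was 245 higher and 94 lower, and with a mean of at least 50 it was 143 and 43. The count was 138 without skip1 induced replicate 1, 136 without skip1 induced replicate 5, 10 without skip2 induced replicate 1, when of the genes named only Cyp4a12a, Hsd3b5, Ces3a and Igfbp2 were still called, and 13 with depth as a covariate, when Cyp4a12a, Hsd3b5, Elovl3, Ces3a, Mup3, Igfbp2 and Eppk1 were still called. Without skip2 induced replicate 2, Hmgcs1, Nid1, Elovl3, Ahsg, Notch2, Fabp1, Alas2, Eppk1, G6pc and Cyp7b1 were not called, and some of these, and Slc1a2, also lost the call without 1 skip1 induced replicate, while Ctnnb1 was called without skip1 induced replicate 2. Named genes that lost the call without skip2 induced replicate 1 kept a median of 90% of their log2 difference (44.8% to 118%). Glul was then at 2.51 and H19 at -4.20. With depth as a covariate, the 19 named genes that lost the call kept a median of 106% (23% to 133%). Glul was then at 3.04, H19 at -5.55 and Hmgcs1 at -0.233. Over all 204 genes called higher, the median was 1.57, or 1.03 without skip2 induced replicate 1 and 0.879 with the covariate.

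**Figure D2:**
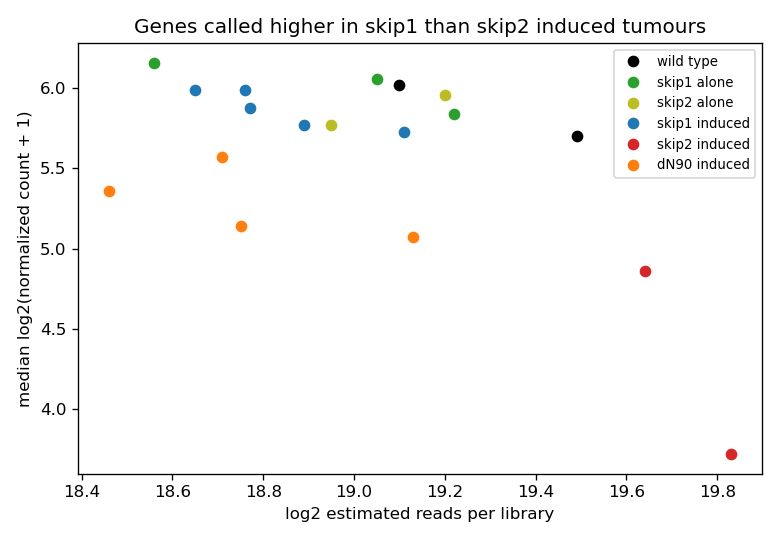
Median log2(normalized count + 1) of the 204 genes called higher in skip1 than in skip2 induced samples, plotted against log2 estimated reads for each of the 18 libraries. The 2 skip2 induced libraries lie at 3.72 and 4.86, and the other libraries lie between 5.07 and 6.16.

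Skip1 induced samples were then compared with dN90 induced samples, whose label names a truncated beta-catenin. Ctnnb1 was higher with skip1 by 2.25 on the log2 scale (SE 0.20, limma adjusted p = 1.63e-07) and Glul by 2.08 (SE 0.44), with Slc1a2 (2.21) and Slc13a3 (1.94) in the same direction. The groups overlapped for Glul, at 558.4 and 500.4 in skip1 induced replicates 1 and 2 and 564.7 in dN90 induced replicate 1. The remaining skip1 induced libraries lay between 1227 and 1910, and the remaining dN90 induced libraries between 86.43 and 408.1. Pericentral genes were higher in 5 of 18 cases, or 6 with 1 lower when adjusted over the list alone, and that list's adjusted p was 0.00868, or 0.49 with an estimated correlation. Periportal genes were higher in 7 of 17 cases, or 9 when adjusted over the list alone, among them Cyp2f2 (4.83), Hsd17b6 (3.17), Sds (2.89) and Hal (2.76). The periportal list passed camera (adjusted p = 4.91e-07) but not with an estimated correlation (adjusted p = 0.228). All 7 male-biased genes were higher, with Mup20, the gene of a urinary pheromone, at 6547 ± 1009 against 317 ± 162 and Cyp4a12a higher by 4.95, and that list held with an estimated correlation (adjusted p = 0.000301).

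Of 24 hepatocyte function genes 5 were higher, also when adjusted over the list alone, including G6pc (2.35), Cyp3a11 (2.31), Fabp1 (2.23) and Ttr (1.89), and the list's adjusted p was 0.0223, or 0.573 with an estimated correlation. Ces3a (5.13), Mup3 (4.98), Serpina3k (4.95), Slco1a1 (3.44) and Cyp7b1 (2.11) were higher as well. The latter pair belongs to the bile acid list, with 5 of 14 higher, or 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.000631, or adjusted p = 0.255 with an estimated correlation). Markers of other cells moved with them: endothelial markers were higher in 4 of 9 cases, or 6 when adjusted over the list alone, among them Clec4g (1.25), Cdh5 (0.94) and Kdr (0.75). The macrophage list, with adjusted p = 0.0468, or 0.49 with an estimated correlation, held 3 of 10 higher members, the same number when adjusted over the list alone, the Kupffer cell markers Vsig4 (1.07), Cd5l (1.03) and Clec4f (1.03). The endothelial list's adjusted p was 1.46e-05, or 0.05 with an estimated correlation. Stellate and fibroblast genes had a median of 0.51 with 0 of 8 called by limma, also when adjusted over the list alone (2 had an unadjusted p under 0.05), in a list with an adjusted p = 0.0104, or adjusted p = 0.228 with an estimated correlation. The YAP target genes Amotl2 (-1.72) and Ptpn14 (-1.54) were lower, 2 of 12 in that list, or 6 when adjusted over the list alone, and the list's adjusted p was 0.00668, or 0.0719 with an estimated correlation. H19 (-2.97) was lower, as were 6 of 20 cholesterol synthesis genes, or 7 when adjusted over the list alone, among them Lss (-0.88), a list with an adjusted p = 3.06e-06, or 0.228 with an estimated correlation. Fmo2 (-2.74), Selenbp1 (-1.69), Ahnak (-1.69), Por (-1.47) and Sult1a1 (-1.30) were among the other genes that were lower. Axin2 (0.21), Mki67 (0.52), Yap1 (0.10) and Alb (0.69) did not pass the test. In all, 305 of 6592 genes were called, 209 higher and 96 lower with skip1, and voom on estimated reads gave 164 higher and 176 lower. Slc1a2, Cdh5, Kdr, Vsig4, Cd5l, Clec4f and Por were not called without dN90 induced replicate 3, nor Lss without dN90 induced replicate 1 or 2, and of these all but Clec4f also lost the call without another single library. On the first principal component skip1 induced replicates 1 (4.81) and 2 (-7.48) stood nearer to the libraries without the induced condition (-45 to -36.2) than the other 3 (14.3 to 24.7). Without both, 253 genes were called, 152 higher and 101 lower, among them G6pc, Cyp3a11, Fabp1 and Ttr but not Slc1a2 or Kdr. The 2 named calls lost there kept 97% and 105% of their log2 difference.

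Skip2 induced samples were compared with dN90 induced samples. Ctnnb1 was higher with skip2 (1.47, SE 0.26, limma adjusted p = 0.00892), and Mup20 stood at 2603 ± 119 (n = 2) against 317 ± 162 (n = 4), a log2 difference of 3.15. Mup20 was the only 1 of 7 male-biased genes called with either adjustment (list median 0.461, camera adjusted p = 0.014, or 0.31 with an estimated correlation). Of 24 hepatocyte function genes 2 were higher with either adjustment (camera adjusted p = 0.00897, or 0.767 with an estimated correlation). C8a, a complement gene (2.58), Serpina1e (2.73), Mug2 (2.15), Cyp3a11 (1.89), Ttr (1.39), Abcb11, the bile salt export pump (1.06), and the collagen gene Col3a1 (1.47) were higher. Igfbp2 was higher too, at 170 ± 18.1 against 63.1 ± 24.6. Periportal genes were higher in 4 of 17 cases, or 6 when adjusted over the list alone, Hsd17b6 (3.79), Cyp2f2 (2.98), Hal (2.17) and Sds (2.11), and that list's adjusted p was 5.73e-07, or 0.31 with an estimated correlation. Lists of other cells moved the same way: stellate and fibroblast genes had a median of 1.08 with 1 of 8 higher, Col3a1, or 2 when adjusted over the list alone (adjusted p = 0.00537, or 0.31 with an estimated correlation). Endothelial markers had a median of 0.557 with 0 of 9 called by limma (3 had an unadjusted p under 0.05), or 3 when adjusted over the list alone (adjusted p = 0.014, or 0.31 with an estimated correlation). Pkd2l2 (-2.11), Zscan30 (-2.08), Psip1 (-1.89), Snhg14 (-1.86) and Srpk2 (-1.84) were lower. Glul (-0.77), Axin2 (0.03), Mki67 (0.63), Yap1 (0.19) and Alb (1.23) did not pass the test. The 200 called genes comprised 38 higher and 162 lower with skip2. The count was 7 without skip2 induced replicate 1, when of the genes named only Mup20, C8a, Mug2 and Hsd17b6 were still called, 308 without skip2 induced replicate 2, 115, 36 and 112 without dN90 induced replicates 2, 3 and 4, 7 with only these groups in the fit and 0 with depth as a covariate. Of the genes named, Cyp2f2, Hal, Sds, Cyp3a11, Igfbp2, Ttr and Abcb11 were not called without skip2 induced replicate 2, and these, Col3a1, Psip1 and Snhg14 were not called without dN90 induced replicate 3; without other dN90 induced replicates some of them, and Serpina1e, lost the call. Named genes that lost the call without skip2 induced replicate 1 kept a median of 101% of their log2 difference (38.4% to 138%). Ctnnb1 was then at 1.49 and, among the genes that shrank, Pkd2l2 was at -1.07 and Snhg14 at -0.72. Most named genes were picked for large differences, so they do not stand for all genes that lost the call.

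Either isoform alone was compared with wild type liver to ask what it does without the induced condition. Ctnnb1 had means of 141 with skip1 alone and 160 with skip2 alone against 138 in wild type liver. This gene therefore gives no sign of the transgene in those samples, and few called genes do not show that an isoform has no effect. For skip1 alone, limma called 0 genes (272 had an unadjusted p under 0.05) and voom called 0. The galactokinase gene Galk1 (-2.17) was called without skip1 alone replicate 1, Gse1 (-2.61) without skip1 alone replicate 2 and the transcription factor gene Mafk (2.87) without wild type replicate 2, genes that were looked up after the calls were seen. Ctnnb1 (0.03), Glul (-0.31), Alb (0.46), Axin2 (-0.18), Mki67 (-0.39) and Yap1 (0.20) did not pass the test. For skip2 alone, Saa2, an acute-phase serum amyloid gene (chromosome 7, 46751790 to 46754313) that has close paralogs, was called, at 1984 ± 1512 (n = 2) against 40.8 ± 52.9 (n = 2), a log2 difference of 6.49 (SE 1.02, limma adjusted p = 0.0183). It was no longer called without either skip2 alone replicate, without wild type replicate 1, with a mean of at least 50 or with only these groups in the fit, when Lcn2 and Orm2 were called instead. Saa2 kept 86.6% and 113% of its log2 difference without skip2 alone replicates 1 and 2 and 67.9% without wild type replicate 1. With a mean of at least 50 or only these groups it kept 100%. Voom called 4 genes, Saa2, its paralog Saa1 (4.12), the acute-phase gene Orm2 (3.67) and Hsd17b6 (-1.92). Ctnnb1 (0.21), Glul (0.09), Alb (0.41), Axin2 (-0.48), Mki67 (0.42) and Yap1 (0.10) did not pass the test.

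Skip1 induced samples were compared with skip1 alone. Ctnnb1 was higher by 2.45 (SE 0.22, limma adjusted p = 2.73e-07). Proliferation genes were higher in 4 of 8 cases, also when adjusted over the list alone, with Mki67 at 3.80, Top2a at 3.17 and Mcm6 at 2.46. Wnt feedback genes were higher in 4 of 6 cases, or 5 when adjusted over the list alone, with Tnfrsf19 at 2.83, Axin2 at 1.80 and Ccnd1 at 1.78, and YAP targets in 6 of 12, or 7 when adjusted over the list alone, with Ajuba at 3.12, Myof at 2.23 and Ccn1 at 1.81. These 3 lists held with an estimated correlation (adjusted p = 0.0275, 0.0152 and 0.0143). The biliary list's Spp1 (4.46), Bicc1 (3.61) and Pkhd1 (2.74) were higher, 3 of 5 with either adjustment, as were Anxa5 (2.29), Flna (2.01) and Jag1 (2.32).

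Periportal genes were lower in 15 of 17 cases, or 17 when adjusted over the list alone, including Hal (-3.45), Etnppl (-3.04), Cyp2f2 (-2.93) and Gls2 (-2.60), and hepatocyte function genes in 16 of 24, or 19 when adjusted over the list alone, including Cyp3a11 (-2.43), the urea cycle gene Otc (-2.11) and Alb (-1.78). These lists had an adjusted p = 9.6e-12 and 3.38e-11 with the preset correlation, and an adjusted p = 0.0552 and 0.0637 with an estimated correlation. Male-biased genes were lower in 6 of 7 cases with either adjustment, with Cyp7b1 at -2.98 and Hsd3b5 at -2.56, and that list held with an estimated correlation (adjusted p = 0.0181). A set of 15 Mup genes (without Mup3, Mup20 and Mup21), which share reads, summed to 4826 ± 4224 (n = 5) against 46570.3 ± 14791 (n = 3). Macrophage markers were higher in 7 of 10 cases, or 9 when adjusted over the list alone, with Lyz2 at 1.38 and C1qb at 1.35 (adjusted p = 3.68e-06, or 0.0508 with an estimated correlation). Stellate and fibroblast genes were higher in 3 of 8, or 4 when adjusted over the list alone, with Col1a1 at 2.40 (adjusted p = 0.0104, or 0.112 with an estimated correlation). Of 9 endothelial markers limma called 0, also when adjusted over the list alone, and 0 had an unadjusted p under 0.05 (adjusted p of the list = 0.425). Interferon genes were higher in 4 of 6 cases with either adjustment, with Ifit2 at 3.28 and Ifit3 at 2.17 (adjusted p = 0.0149 with an estimated correlation). Antigen presentation genes were higher in 4 of 11 with either adjustment, with H2-Eb1 at 2.26 and H2-Ab1 at 2.06 (adjusted p = 0.000215, or 0.0977 with an estimated correlation). Glul (1.17, limma adjusted p = 0.113) and Yap1 (-0.21) did not pass the test. In all, 971 genes were called, 432 higher and 539 lower, or 117 and 428 among genes with a mean of at least 50 and 810 and 539 without a filter. Upper-quartile rescaling, which moved the median difference of all genes from -0.0222 to 0.106, gave 593 higher and 388 lower, quantile normalization gave 398 and 303, without a call for Alb, and voom on estimated reads, with a median of 0.478, gave 1438 and 192. Normalized counts summed to 625660 to 651234 in skip1 alone and 415528 to 524243 in skip1 induced libraries. Scaling by library totals, as voom did, therefore raised the induced values of all genes. Without skip1 alone replicate 3 the count was 568 and Etnppl was not called, nor was it without skip1 alone replicate 2 or Axin2 without skip1 alone replicate 1, while Glul was called without skip1 induced replicate 2, with quantile normalization and with voom.

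Skip2 induced samples were compared with skip2 alone. Ctnnb1 was higher, at 451 ± 9.06 against 160 ± 24.1 (n = 2 each, limma adjusted p = 0.00173), as were the proliferation genes Mki67 (3.10) and Top2a (2.95), the Wnt targets Tnfrsf19 (3.01) and Ccnd1 (2.70), the biliary list's Spp1 (4.39) and Bicc1 (5.31), Emp2 (5.39), Nid1 (3.40) and the collagen gene Col1a1 (3.75). Of 8 proliferation genes 3 were higher and 1, the mitotic kinase gene Aurka (-1.59), was lower with either adjustment, and the list's adjusted p was 0.0466, or 0.248 with an estimated correlation. Wnt feedback genes were higher in 2 of 6 cases, or 4 when adjusted over the list alone (adjusted p = 0.0319 with an estimated correlation), and stellate and fibroblast genes were higher in 3 and lower in 1 of 8 with either adjustment (adjusted p = 0.0558). Of 12 YAP targets 6 were higher, also when adjusted over the list alone, with Ajuba at 3.31, Ccn1 at 3.28 and Myof at 3.21 (adjusted p = 0.00647 with an estimated correlation). All 3 Notch genes measured were higher with either adjustment, including Jag1 (1.81) and Notch1 (1.52), in a list with an adjusted p = 0.00267, or adjusted p = 0.0705 with an estimated correlation, as were Ifit2 (3.01) and H2-Eb1 (2.32). Pericentral genes were lower in 8 and higher in 1 of 18 cases, or 9 and 3 when adjusted over the list alone, the lower ones including Cyp2c29 (-4.25), Slc1a2 (-3.28) and Oat (-2.62), with Glul at -2.08 (limma adjusted p = 0.0374), and that list's adjusted p was 0.0257, or 0.482 with an estimated correlation. Periportal genes were lower in 8 of 17 cases, or 12 when adjusted over the list alone, with Cyp2f2 at -4.68, Hal at -3.14 and Gls2 at -2.69 (adjusted p = 1.05e-05, or 0.2 with an estimated correlation). Hepatocyte function genes were lower in 11 of 24, or 16 when adjusted over the list alone, with G6pc at -2.76, Cyp3a11 at -2.67 and Fabp1 at -2.56 (adjusted p = 1.8e-07, or 0.16 with an estimated correlation), and all 7 male-biased genes were lower with either adjustment, with Hsd3b5 at -6.81 (adjusted p of the list = 0.00647 with an estimated correlation). Saa2 was at 4.22 ± 0.77 against 1984 ± 1512. Axin2 (1.92, SE 0.65), Alb (-1.19) and Yap1 (-0.02) did not pass the test. In all, 985 genes were called, 430 higher and 555 lower, or 114 and 412 among genes with a mean of at least 50, 624 and 532 without a filter, 554 and 410 with upper-quartile rescaling and 436 and 341 with quantile normalization. With depth as a covariate 767 genes were called, 323 higher and 444 lower, of which 609 were among the 985. The 7 named genes that lost the call there kept a median of 76.1% of their log2 difference (68% to 116%). The count was 346 without skip2 induced replicate 1, and 508 and 576 without skip2 alone replicates 1 and 2, and Glul, Slc1a2, Oat, Hal, Gls2, Cyp3a11, Top2a, Aurka, Jag1 and Notch1 each lost the call in at least 1 of these, all of them without skip2 induced replicate 1; Glul was also not called without skip2 induced replicate 2 or with another scaling, and Notch1 was not called without skip2 induced replicate 2.

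Subtype A was compared with subtype B on z-scores of the 1659 selected genes. Gpnmb, a glycoprotein gene of macrophages and tumour cells, was higher in subtype A by 1.59 SD (SE 0.27, limma adjusted p = 0.000787). Among the other genes that the naming rule picked, the manganese transporter gene Slc30a10 (1.27), the water channel gene Aqp8 (1.15), Mup20 (1.11), Mapk15 (1.10), Ces2e (1.04), Cyp2c67 (1.01) and Wfdc2 (1.01) were higher. Mcf2l (-1.17), Anxa3 (-1.14), Kirrel (-1.13), Slc27a1 (-1.11) and Elf4 (-1.10) were lower in subtype A. YAP targets were lower in 5 of 7 cases, also when adjusted over the list alone, among them Tgfb2 (-1.01), Ankrd1 (-0.80), Myof (-0.74) and Ptpn14 (-0.71). Axin2, a Wnt feedback gene (-0.95, limma adjusted p = 0.0258), and the proliferation genes Mki67 (-0.58) and Top2a (-0.63) were lower, 1 of 4 and 2 of 13 in their lists, or 0 and 0 when adjusted over the list alone. Interferon genes were lower in 3 of 8 cases with either adjustment, with Mx1 at -1.01 and Oasl2 at -0.92.

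Hepatocyte function genes were higher in subtype A in 12 of 18 cases, or 13 when adjusted over the list alone (Apob 0.58, F9 0.50), fatty acid oxidation genes in 9 of 10 (Vnn1 0.76), bile acid genes in 9 of 12 (Cyp8b1 0.62, Abcb11 0.55) and endothelial markers in 4 of 4 (Clec4g 0.48, Kdr 0.45), the same counts for these 3 lists when adjusted over the list alone. Markers within a list did not all move together: Prom1 was at 0.91 and Cd44 at -0.74 among progenitor genes, and Cd14 was at 1.05 and Trem2 at -0.92 among macrophage genes. S100a6 (-0.90) was lower. Afp (-0.68) and Alb (0.24) did not pass the test. Limma called 1014 genes, 668 higher and 346 lower in subtype A. The genes were selected by the authors, so list counts are not independent evidence of direction. Calls were lost for Axin2, Mki67, Top2a, Cyp8b1 and Cd44 without subtype A replicate 1, for Mx1, Oasl2 and Vnn1 without replicate 2, for Axin2, Mki67, Top2a, Vnn1 and Ankrd1 without replicate 3, for Oasl2, Vnn1 and Ankrd1 without replicate 4, and for Top2a without subtype B replicate 7 or 8. Genes that lost the call without subtype A replicates 1, 2, 3 and 4 kept a median of 69.9%, 82.7%, 101% and 89.6% of their difference. The exact permutation per gene did not call Mki67, Top2a, Oasl2 or Vnn1.

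Both subtypes differed from the control with YAPS127A in most of the 1659 selected genes, 1614 for subtype A (692 higher, 922 lower) and 1653 for subtype B (731 higher, 922 lower). In subtype A, Prom1 (2.88), Abcb1a (2.75), Cd14 (2.72), Myc (2.39), Ccnb2 (2.16), Ajuba (2.14), Mki67 (1.92) and Axin2 (1.19) were higher than in the control, and Ngef (-2.68), Sds (-2.43), Arg1 (-2.42) and Alb (-2.30) were lower. In subtype B, Ccdc120 (2.63), Ptpn14 (2.61), Mki67 (2.50), Myc (2.48), Ccnb2 (2.45), Axin2 (2.14), Usp18 (2.09), H2-Aa (1.81) and Afp (1.75) were higher, and Pcbd1 (-2.64), Cps1 (-2.61), Ftcd (-2.61) and Alb (-2.54) were lower. Afp in subtype A (1.07) did not pass the test, and Axin2 in subtype A did not without subtype A replicate 4. Of the 1014 genes called between the subtypes, 997 had their subtype A mean between those of the control and subtype B. This count may come from the authors' selection of genes, and both comparisons share the subtype B libraries.

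**Figure D3:**
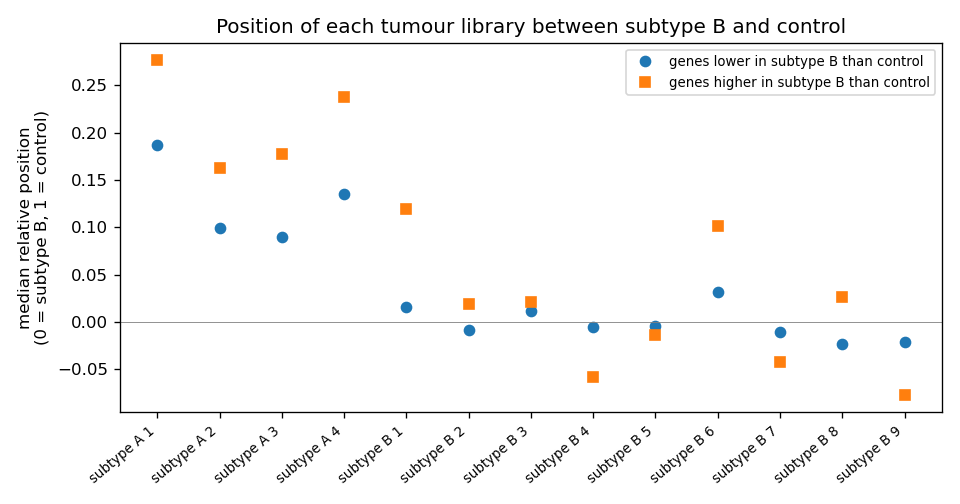
Median relative position of each tumour library between subtype B (0) and the control (1), over 922 genes lower and 730 genes higher in subtype B than in the control; each subtype B library was set against the other subtype B libraries. The 4 subtype A libraries lie between 0.0898 and 0.277.

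Whether the isoforms differ along the same genes as the subtypes was tested over 770 genes called between the subtypes and kept in the normalized counts. Across genes, which are not independent replicates, Pearson r between both differences was 0.372 and 71.4% of genes had the same sign. Of the 21 splits of the skip1 and skip2 induced libraries, 10 gave an r as large (exact two-sided permutation p = 0.476, smallest possible 0.0476), and 11 gave as large a share (p = 0.524).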

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

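The tests of library depth, of 1 library and of admixed liver (for both patterns) were chosen after the results they address were seen, whereas the other splits of the samples were planned before the data were examined. Among the genes named, 214 sets of values of a gene within a group of 4 to 9 samples were searched for a single sample far from the rest, which chance alone gives in about 11, and 15 were found. In dN90 induced replicate 3, the normalized count of Cd5l was 21.3 (58.6 to 63.7 in the others) and that of Fabp1 was 30.1 (51.9 to 56.6), and Sds was 0.787 in dN90 induced replicate 1 and 0 in the others. That value of Sds was 1 estimated read, since the step of that library was 0.786515. In skip1 induced replicate 2, Ifit3 was 4.63 (15.3 to 17.6) and Tat was 618 (157 to 218). In subtype A replicate 1 the z-score of Arg1 was -0.164 (-0.412 to -0.375 in the others), that of Ccnb2 was -0.471 (0.372 to 0.538) and that of Cyp2c67 was 1.11 (0.0435 to 0.186). In subtype A replicate 2, Mx1 was -1.05 (-0.381 to -0.315) and Tgfb2 was 0.18 (-0.637 to -0.556), and in subtype A replicate 3, Elf4 was -0.215 (-0.448 to -0.419) and Kdr was -0.283 (-0.049 to -0.0048). In subtype B replicate 6, Axin2 was 2.21 (0.0169 to 1.04), Cyp2c67 was -0.139 (-0.824 to -0.546) and Kdr was -0.125 (-0.718 to -0.433).

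Of 93 genes that the naming rule gave for the comparisons of normalized counts, the log2 difference between induced and alone samples differed between the isoforms for 5, by limma's moderated test of the interaction adjusted over 6592 genes. A positive value means a weaker fall with skip1 for 4 of them. Hsd3b5 was at -2.56 with skip1 and -6.81 with skip2 (4.25 apart, adjusted p = 0.00138), Cyp4a12a at -1.36 and -5.74 (4.39, adjusted p = 0.00138) and Ces3a at -1.18 and -4.32 (3.14, adjusted p = 0.0354). Saa2 was at -1.36, without a call, and -8.33 (6.98, adjusted p = 0.0201), where the skip2 alone level was high. Igfbp2 was at -1.85 with skip1 and 2.19 with skip2 (-4.04, adjusted p = 0.00138).

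The 204 genes higher in skip1 than in skip2 induced samples had a median log2 difference of 1.57 (SE 0.357). In this paragraph SE beside a median is the median of the single genes' limma SEs, not the error of the median. Removing skip2 induced replicate 1 left 8 of them called, against 168 without replicate 2, so the number of calls rests on that library. Their median without it was 1.03 (SE 0.406), so a smaller difference with a larger error was left, in genes that had been chosen with that library included. For the 6 male-biased genes it was 3.21 (SE 0.55), with 2 of 6 called, or 3 of 6 without replicate 2. Within the groups of the other 11 libraries, deviations of their median went with depth at Pearson r = -0.643 (two-sided exact permutation p = 0.0903, adjusted p = 0.151 over 5 relations) and Spearman rho = -0.727 (p = 0.0573, adjusted p = 0.127), and r was -0.496 without the 2 libraries farthest from the median of these depth deviations. In the same 11 libraries r was -0.429 for the other 6388 genes (p = 0.271, adjusted p = 0.339) and 0.339 for the 6 male-biased genes (p = 0.406, adjusted p = 0.406, exact permutation). With the skip1 libraries included r was -0.687 (p = 0.0247, adjusted p = 0.0618, permutation within groups) and rho was -0.735 (p = 0.0175, adjusted p = 0.0875). The fifth relation took the 100 of these genes that were also lower in skip2 than in dN90 induced samples. In the same libraries their r was -0.661 (p = 0.0151, adjusted p = 0.0618) and their rho -0.529 (p = 0.0762, adjusted p = 0.127), by the same permutation. With depth as a covariate the median was 0.879 (SE 0.529) and 9 of 204 genes were called, because the difference was smaller and its error larger, so depth and isoform cannot be told apart for these genes, because both skip2 induced libraries were the deepest. For the 6 male-biased genes the median was 3.55 (SE 0.422) before and 3.75 (SE 0.658) with the covariate. With the covariate, 3 of 6 were still called. Their median difference did not shrink, but these genes had been chosen as called in this same comparison. The 2 skip2 induced libraries were the deepest for them too, so the covariate cannot tell depth and isoform apart here either. An effect of the isoform stays open and untested.

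Of the genes higher in skip1 than in dN90 induced samples, 67 were set against the liver they would need as admixture. They were genes other than Mup genes, with high values in wild type and skip1 alone livers. Their values in dN90 induced samples were far lower, and they were not taken from a hepatocyte list. The share of liver that their median needs was above the share that the Mup transcripts allow in 5 of 5 skip1 induced libraries, from 14.7% against 4.04% in replicate 3 to 52.2% against 38.5% in replicate 2. The allowed share took the lowest sum of 15 Mup genes (without Mup3, Mup20 and Mup21) in a sample without the induced condition, 31150, as pure liver. The 67 genes were chosen as higher in these same skip1 induced libraries while the Mup genes were not, which by itself can raise the needed share. The comparison therefore cannot decide whether admixed liver is the source. Liver beside the tumours with fewer Mup transcripts also stays open. A difference between the beta-catenin forms stays open and untested.

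Subtype A lay between the control and subtype B for 997 of 1014 genes. The authors selected the genes, 1653 of 1659 were called between subtype B and the control, and both comparisons share the subtype B libraries. That count may therefore come from the selection, and the share expected without a difference is not known. On a scale from subtype B (0) to the control (1) the mean profile of subtype A lay at 0.13 for genes lower in subtype B and at 0.22 for genes higher in subtype B, and the second shift was larger in 4 of 4 libraries. Admixed liver would bring liver transcripts at least as strongly, but the gap between both shifts was 0.0634 to 0.103 in subtype A and -0.057 to 0.103 in the 9 subtype B libraries, each set against the others, so gaps of that size also arose within subtype B. Admixed liver and a difference between the subtypes therefore cannot be told apart for these genes, and an effect of how the authors scaled the libraries stays open. For 17 genes, all higher in subtype A, subtype A lay beyond subtype B.

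Other splits of the samples into groups of the same sizes were compared with the real ones by the number of genes called. The real split was the only 1 to call as many in 100 drawn of 715 splits for subtype A against B (1014 genes, highest other 141), in 35 splits for subtype A against the control (1614, highest other 1587), in 100 drawn of 220 for subtype B against the control (1653, highest other 1431), in 100 drawn of 126 for skip1 against dN90 induced (305, highest other 118) and in 56 for skip1 induced against alone (971, highest other 710). For skip1 against dN90 induced and for skip1 induced against alone, a chance split of these libraries is unlikely at that level. Chance between animals is not excluded, because the labels do not say that libraries of a group came from separate animals. For the subtypes and their control the splits decide nothing, because the z-scored genes were selected by the authors and other splits of the samples on genes picked for the real groups would call fewer. Groups of 2 in the skip2 and wild type comparisons were not split.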

How the results depend on the processing

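Voom on estimated reads, depth as a covariate, leaving out skip1 induced replicates 1 and 2 together (the nearest to liver without the induced condition), rescaled z-scores and the exact permutation per gene were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because replicate numbers were given by order and pair no samples. For the z-scores, other pseudocounts, filters and scalings could not be run, nor could a fit without samples whose labels disagree, since no subtype sample has such labels. Leaving out 1 replicate of a pair assumed that the lone sample varies like the other groups. Counts for the 3 subtype comparisons and for skip1 against dN90 induced stayed within 1.5 times the reported ones under each alternative run (764 to 1187 for subtype A against B, 205 to 362 for skip1 against dN90). Of 3979 values of named genes under alternatives, 3629 kept direction and side of the threshold, 285 lost a call, 16 gained one, and 49, all without a call, changed sign or became 0. The correlation of the subtype and isoform differences lay between 0.168 and 0.542. With 1 replicate left out the smallest p that the splits can give was 0.167 without a skip2 and 0.0667 without a skip1 induced replicate, so those p-values say nothing about stability, and with all of these libraries (smallest 0.0476) p was 0.333 to 0.524. Estimated reads of 361772 to 933147 limit what low genes can show. Except where fewer genes or samples were tested, and for the shift that voom's scaling by library totals brought, the cause was not tested.

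The count for skip1 against skip2 induced was 400 with array weights, 382 with voom and 13 with depth as a covariate, and 10 to 342 when 1 replicate was left out. For skip2 against dN90 induced it was 7 with only those groups, 0 with depth as a covariate and 7 to 308 with 1 replicate left out. For skip1 alone it was 0 to 1 with 1 replicate left out. For skip2 alone it was 4 with a pseudocount of 5, 2 without a filter, 0 with a mean of at least 50, 2 with only those groups (Lcn2 and Orm2, not Saa2), 2 with array weights, 4 with voom and 0 to 1 with 1 replicate left out. For skip1 induced against alone it was 545 with a mean of at least 50, where fewer genes were tested, 1630 with voom and 568 to 1217 with 1 replicate left out. For skip2 induced against alone it was 526, 1786 (1545 higher and 241 lower, at a median of 0.577 over all genes) and 346 to 788. Normalized counts summed to 428990 and 485745 in the skip2 induced libraries and to 694092 and 694773 with skip2 alone. Voom's scaling by library totals therefore raised induced values there too. With an estimated correlation 14 of 161 list tests passed, against 53.

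Log2 differences of uncalled genes that changed sign were, with depth as a covariate, Mki67 at 1.12 and Alb at 0.156 in skip1 against skip2 induced, Mki67 at -0.712 and Axin2 at -1.45 in skip2 against dN90 induced, Ctnnb1 at -0.00261, Axin2 at 0.358 and Mki67 at 0.0916 in skip1 alone, and Yap1 at 0.0142 in skip2 induced against alone. With voom they were Axin2 at -0.0771 in skip2 against dN90 induced, Ctnnb1 at -4.645e-05 in skip1 alone, Glul at -0.0738 and Yap1 at -0.0798 in skip2 alone, and Yap1 at 0.343 in skip1 and 0.6075 in skip2 induced against alone. With quantile normalization they were Ctnnb1 at -0.0701 in skip1 alone, Glul at -0.0838 in skip2 alone, Yap1 at 0.0822 in skip2 induced against alone, and Alb at 0 in skip1 alone, skip2 alone and skip2 induced against alone. Upper-quartile rescaling gave Yap1 at 0.151 in skip2 induced against alone, and array weights gave Axin2 at -0.0126 in skip2 against dN90 induced and 0.06725 in skip1 alone. Without skip1 induced replicates 1 and 2, Mki67 was at 0.160 against skip2 and Yap1 at -0.0923 against dN90 induced.

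With 1 replicate left out, ranges that crossed 0 were -0.0950 to 0.457 for Axin2, -0.446 to 0.215 for Mki67 and -0.230 to 0.0850 for Yap1 in skip1 against skip2 induced, and -0.0459 to 0.498 for Axin2 and -0.0376 to 0.333 for Yap1 in skip1 against dN90 induced. They were -0.245 to 0.317 for Axin2 in skip2 against dN90 induced and -0.184 to 0.143 for Yap1 in skip2 induced against alone. In skip1 alone they were -0.993 to 0.642 for Axin2, -0.0710 to 0.136 for Ctnnb1, -0.875 to 0.368 for Mki67 and -0.120 to 0.513 for Yap1. In skip2 alone they were -1.30 to 0.335 for Axin2, -0.0159 to 0.2045 for Glul, -0.00422 to 0.851 for Mki67 and -0.217 to 0.416 for Yap1.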

Other observations

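Values here were chosen after they were seen. In the test of whether the difference between induced and alone samples differed between the isoforms, limma called 11 of 6592 genes, 9 with a positive and 2 with a negative value for skip1 minus skip2 (662 had an unadjusted p under 0.05). The sulfotransferase gene Sult2a8 fell less with skip1 (-1.44) than with skip2 (-5.32), 3.88 apart. Saa1, a paralog of Saa2, was at -1.37, without a call, and -7.45 (6.08 apart). Itih5 was at -1.57 with skip1 and 0.73, without a call, with skip2 (-2.30). Glul (3.25, adjusted p = 0.135) and Ctnnb1 (0.95, adjusted p = 0.386) did not pass that test.

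Among the z-scored genes, cholesterol synthesis genes were higher in subtype A than in subtype B in 4 of 5 cases, glycolysis genes in 4 of 6 and male-biased liver genes in 5 of 7, the same counts when adjusted over the list alone, and antigen presentation genes passed in 0 of 7 (limma; median -0.745 SD). In skip1 alone against wild type liver, none of 20 cholesterol synthesis genes was called, and the list had an adjusted p = 0.0435, or adjusted p = 0.892 with an estimated correlation. The sum of 15 Mup genes, without Mup3, Mup20 and Mup21, was 78105.5 ± 17009.5 (SD, n = 2) in wild type liver, 80131 ± 2799 (n = 2) with skip2 alone, 307 ± 342 (n = 2) in skip2 induced and 81.4 ± 30.3 (n = 4) in dN90 induced samples.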
